A study of Arabidopsis thaliana with 21 samples.

How the data were processed

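RNA was measured by sequencing in root tips of 5-day-old Arabidopsis thaliana plants. Each library came from 50 tips of 1 to 2 mm, RNA was extracted with a Qiagen kit, and a sequencing company made and sequenced the libraries, per the labels. The 21 libraries formed 7 groups of 3, and the labels call the 3 libraries of a group biological replicates. Groups were taken from the genotype and treatment labels, and replicate numbers from the labels as well.

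The deposited files, 1 per library, give for each transcript an estimated (expected) number of reads, a TPM value, a length and an effective length, per the file headers. Per the submitters' processing notes these values came from Salmon 1.3.0 and the TAIR10 build. The library layout, the strand option and any bias correction are not given in the sources used here. Each file held 48268 transcripts of 27586 genes. The deposited expected counts need not be whole numbers, and Salmon divides reads shared by similar transcripts among them, so values of near-identical paralogs, such as neighbouring SAUR genes or small heat shock proteins, are uncertain. Overlapping and antisense genes are uncertain too, because no strand option is stated. The deposited TPM values were used only to check that the files were read correctly, and the deposited effective lengths only for 1 alternative.

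The expected counts were summed per locus and rounded to whole numbers, which moved library totals by at most 2.3e-05%. Symbols came from a gene table of assembly TAIR10.1. It was used for names only and no coordinates were taken from it, because the build differs from the one the submitters name. Of the 27586 loci, 27389 had an entry there and 10372 had a symbol other than the locus tag. Library totals ran from 17.45 to 23.88 M estimated reads. Replicates of a group were compared by a chi-square of their counts over genes, and the mean per gene was between 23.7 and 151 for all pairs, so no library was counted as a duplicate.

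Differential expression was tested with edgeR 4.0.16 in R 4.3.3. All 21 libraries entered 1 quasi-likelihood fit with a coefficient per group, TMM scaling and the default low-count filter by group, which left 19809 genes and 14 residual degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Values per library are given in CPM, computed from the TMM-scaled library sizes, and group values are given as mean ± SD with n = 3. Log2 changes are given with their standard error (SE). The median log2 change of all tested genes lay between -0.015 and 0.023 in every comparison, and between -0.01 and 0.017 with median-of-ratios scaling.

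The comparisons were IAA against mock, PEO-IAA against mock, IAA against PEO-IAA, the HS::AXR3-1 line against Col-0 after the same heat treatment, the XVE>>AXR3-1 line against Col-0 after the same estradiol treatment, and the difference between the effects of both lines. Heat-shocked Col-0 against estradiol-treated Col-0 served as a check of the heat treatment. Treatment and experiment cannot be told apart in that check, so only the heat shock list and the count of genes are given for it.

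A total of 25 gene lists with 354 members was fixed, all found in the files. The 8 marker lists were root hair, cell division, endodermis, xylem, phloem, root cap, non-hair epidermis and green tissue. The other lists were Aux/IAA (without AXR3), auxin inactivation, SAUR, auxin-regulated transcription factors, auxin transport, auxin receptors and ARFs, auxin biosynthesis, gibberellin metabolism, gibberellin perception and response, expansins, XTH, plasma membrane proton pumps, ethylene, cytokinin, brassinosteroid, heat shock, and touch, wounding and jasmonate. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and p-values were adjusted over the 25 lists of a comparison. The same test with an estimated correlation and fry, a rotation test of the list alone, were alternatives.

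Named genes followed a rule. It took AXR3, and then up to 5 genes with the largest rise and 5 with the largest fall among called genes with a mean CPM of at least 5 in the higher group and no overlap between the groups. It added up to 3 called members with the smallest p from the Aux/IAA, inactivation, SAUR, transcription factor and both gibberellin lists, and 1 from each other list. For the difference between the lines it took up to 5 genes each way with a mean CPM of at least 5 in any of the 4 groups, and for the heat check the 4 heat shock members with the smallest p. Other members of a list are named as examples of its count.

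The tests, the groups, the lists, the named-gene rule and the alternative settings were chosen before the data were examined. These alternatives were DESeq2 1.42.0, a fit of each experiment alone, a length offset from the effective lengths, median-of-ratios scaling, no low-count filter, robust empirical Bayes estimation, the replicate number as a block, and leaving out each library in turn. Lists without replicate 1 or replicate 3 of HS::AXR3-1, with either correlation, and lists with the replicate block and an estimated correlation together were added after seeing the data.

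The groups of an experiment share replicate numbers. Same-numbered libraries deviated together from their group means in the experiment with IAA and PEO-IAA (r across genes from 0.52 to 0.78, and 9 of 9 libraries correlated best with their own number) and in the estradiol experiment (0.49 to 0.70, 6 of 6). The numbers were therefore read as pairing the libraries in those experiments, from the data and not from a label, and the fit with the block kept 8 residual degrees of freedom. In every comparison the main fit, the fits with a library left out and the splits did not use this block.

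Both chemical comparisons use the same mock libraries. Changes against that mock were therefore also computed for 100 simulated pairs of unchanged groups. The mock libraries were not split, because each part could not keep 2 of them.

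Where a group had 0 counts of a gene, a lower bound of the fold was computed against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% interval. Such intervals and bounds cover counting error only.

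The steps were tested on simulated counts of 19679 genes with 200 changed genes. For IAA against mock 17.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, and 5% of calls were false. For XVE>>AXR3-1 against Col-0 these were 14.9%, 52.2% and 93.9%, with 3.6% false calls. No library and no list was left out.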

Results

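Transcript levels were measured by RNA sequencing in Arabidopsis root tips in 3 experiments with 21 libraries. In the first, Col-0 (the wild type) was treated for 20 min with 10 nM of the auxin indole-3-acetic acid (IAA), with 10 µM of PEO-IAA, or with ethanol as mock. PEO-IAA is a relative of IAA with an added phenyl ketone side chain that acts as an auxin antagonist. In the second, the line HS::AXR3-1 (as in the design text of the series, HS:AXR3-1 in the sample labels) and Col-0 were kept at 37 °C for 40 min and left to recover for 80 min. In the third, an estradiol-inducible line and Col-0 were given 5 µM estradiol for 2 h. That line carries AXR3-1 fused to a red fluorescent protein. Its genotype is labelled XVE:AXR3-1-RFP and the design text of the series names the tag mCherry, and it is called XVE>>AXR3-1 here. No tag is named for HS::AXR3-1. Both lines express, on heat or on estradiol, AXR3-1, a stabilized form of the Aux/IAA protein IAA17, which binds auxin together with TIR1/AFB receptors and represses auxin-responsive transcription. Per the title of the series, the study concerned cell elongation and the perception of auxin and gibberellin.

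Each of the 7 groups had 3 libraries. Totals per library were 20.39 to 22.18 M estimated reads with IAA, 19.28 to 22.18 with PEO-IAA and 18.75 to 20.61 with mock. They were 20.16 to 21.92 M in HS::AXR3-1, 17.68 to 23.88 in heat-shocked Col-0, 17.45 to 22.04 in XVE>>AXR3-1 and 21.22 to 22.12 in estradiol-treated Col-0.

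The level of AXR3 (AT1G04250), which counts reads of the native gene and of the transgene together, was 953 ± 226 CPM (SD, n = 3) in XVE>>AXR3-1 and 156 ± 16.8 in its Col-0. That was a 6.12-fold rise (log2 change 2.61, SE 0.39, edgeR adjusted p = 9.71e-04). In HS::AXR3-1 the mean was 447 ± 364 CPM against 129 ± 30.5 in heat-shocked Col-0, and the 3 libraries of the line held 181, 298 and 861 CPM. This 3.48-fold difference did not pass the test in edgeR (log2 change 1.80, SE 0.38, adjusted p = 0.199), and over the alternative settings the adjusted p ranged from 0.00103 with DESeq2 to 1 in a fit of that experiment alone. Without HS::AXR3-1 replicate 1 it passed (log2 change 2.17, edgeR adjusted p = 0.0132), and without replicate 3 the log2 change was 0.90 (adjusted p = 0.151). The mock, IAA and PEO-IAA groups held 139 ± 15.3, 158 ± 8.91 and 147 ± 12.1 CPM, and AXR3 was called with neither chemical (edgeR adjusted p = 1 for both).

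**Figure D1:**
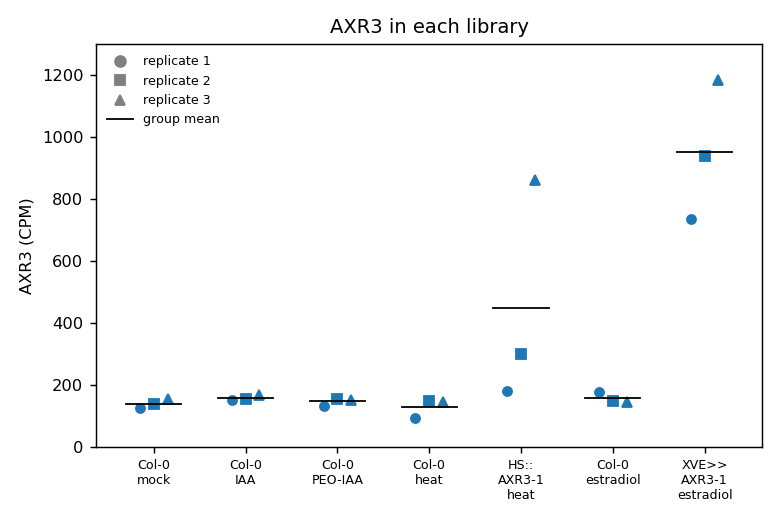
AXR3 level in CPM (linear axis) in each of the 21 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. XVE>>AXR3-1 libraries sit between 734 and 1180 CPM, HS::AXR3-1 libraries spread from 181 to 861, and the other groups have means between 129 and 158.

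The first comparison asked which genes respond to IAA within 20 min. IAA raised early auxin genes in Col-0 root tips. Among the Aux/IAA repressors, IAA5 rose 29.5-fold from 0.295 ± 0.217 to 8.82 ± 1.48 CPM (n = 3 each, log2 change 4.88, SE 0.94, edgeR adjusted p = 0.0444). IAA1 rose 3.45-fold to 82.5 ± 2.78 CPM (SE 0.29, adjusted p = 0.0155) and IAA2 2.04-fold to 221 ± 12.7 CPM (SE 0.18, adjusted p = 0.0256). GH3.1 and GH3.5, which belong to the enzymes that conjugate IAA to amino acids, rose 5.7-fold (SE 0.33, adjusted p = 0.00308) and 2.98-fold (SE 0.26, adjusted p = 0.0201). Genes outside the auxin lists rose as well, among them the MAP kinase gene MPK3, 3.71-fold from 29.8 ± 5.97 to 110 ± 15.9 CPM (SE 0.17, adjusted p = 4.26e-05), and NUDT7, a Nudix hydrolase gene, 3.71-fold to 211 ± 14.3 CPM (SE 0.24, adjusted p = 0.00308).

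In all, 29 genes were higher and 4 lower with IAA, 19 and 2 of them by at least 2-fold. With the replicate number as a block the counts were 111 and 22, and 32 of the 33 calls were kept. The 4 lower genes were AT3G15115 (log2 change -1.14, SE 0.18, edgeR adjusted p = 0.0155), AT1G05660 (-1.06, SE 0.19), AT2G47440 (-0.72, SE 0.14) and AT5G58530 (-0.60, SE 0.11). AT5G47440 rose as well (1.99, SE 0.36). The count of higher genes was 10, 14 and 9 without IAA replicate 1, 2 or 3 and 8, 9 and 6 without mock replicate 1, 2 or 3. The count of lower genes was 0, 2 and 1 without IAA replicates 1, 2 and 3 and 2, 2 and 0 without the mock ones. Of the 15 named genes that were called, GH3.1, MPK3 and NUDT7 kept their call without any 1 library, and the other ones lost it while keeping their sign. IAA5 (log2 change 4.37 to 5.36 over libraries left out), IAA2 (1.00 to 1.08), GH3.5 (1.45 to 1.68), ARF19 (0.96 to 1.21), AT5G47440 (1.81 to 2.27), AT2G47440 (-0.78 to -0.65) and AT5G58530 (-0.64 to -0.58) lost it without any of the 6 libraries. IAA1 (1.70 to 1.88) kept it only without IAA replicate 2, IAA11 (1.13 to 1.39) only without mock replicate 2 and AT1G05660 (-1.24 to -0.80) only without mock replicate 1. HAT2 (0.98 to 1.18) lost it without IAA replicate 1 or 3 or mock replicate 2 or 3, and AT3G15115 (-1.37 to -0.93) without IAA replicate 1 or 2 or mock replicate 3. The fits with a library left out did not use the replicate block. With the block and all libraries, the edgeR adjusted p was 0.00205 for IAA5, 0.00897 for IAA2, 0.00896 for GH3.5 and 6.85e-04 for ARF19.

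Of 26 measured Aux/IAA genes, 4 rose with IAA (IAA1, IAA2, IAA5 and IAA11) and 0 fell, against 8 and 0 adjusted over the list alone, and the list rose as a set (median log2 change 0.49, camera adjusted p = 3.45e-17, adjusted p = 0.044 with an estimated correlation). Of 8 inactivation genes 2 rose (GH3.1 and GH3.5), 4 adjusted over the list alone and 4 with the replicate block, with a list median of 1.46 (camera adjusted p = 2.59e-11, adjusted p = 0.044 with an estimated correlation). Of 17 auxin-regulated transcription factors 2 rose, HAT2 (log2 change 1.06, SE 0.17) and ARF19 (1.09, SE 0.21), 4 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 3.50e-07, adjusted p = 0.0296 with an estimated correlation). None of 10 SAUR genes passed alone and 1 did when adjusted over the list alone, and the set rose (median 0.33, camera adjusted p = 3.50e-07, adjusted p = 0.0097 with an estimated correlation). With the replicate block and an estimated correlation together, an alternative added after seeing the data, the set calls of all 4 lists were lost (adjusted p = 0.266 for Aux/IAA and 0.126 for each other list). SAUR24 had 80 counts with IAA and 2 with mock, a ratio of 36.5 (9.77 to 306).

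The touch, wounding and jasmonate list, a sign of handling, rose with IAA as well. All 11 of its genes were above 0, with a median of 0.87 (camera adjusted p = 3.75e-07, adjusted p = 0.0723 with an estimated correlation), and 3 passed adjusted over the list alone. Its mean log2 CPM was 4.60, 4.95 and 5.81 with IAA, 4.89, 4.73 and 4.63 with PEO-IAA and 3.85, 4.74 and 4.25 with mock. The heat shock list rose too (26 genes, median 0.70, camera adjusted p = 0.00108, adjusted p = 0.512 with an estimated correlation). Auxin biosynthesis was lower as a set (7 genes, median -0.29, camera adjusted p = 0.0156, adjusted p = 0.102 with an estimated correlation), as were the expansins (18 genes, -0.14, 0.00922 and 0.145) and the receptors and ARFs (16 genes, -0.09, 0.0393 and 0.505). Green tissue markers (4 of 8 measured, 0.35) had a camera adjusted p of 0.0393 and 0.145 with an estimated correlation. For the XTH and ethylene lists camera gave an adjusted p of 0.0393 each, lost with an estimated correlation (adjusted p = 0.512 for both) and with the replicate block (0.133 and 0.0777). With the block 1 gene was higher in each of the touch, heat shock, ethylene and auxin transport lists, where 0 were without it. With that block 3 small lists passed, xylem (adjusted p = 0.0258, 0.172 without it), root cap (0.0457, 0.0576) and non-hair epidermis (0.0145, 0.0574). These calls were lost with an estimated correlation in that fit (adjusted p = 0.429, 0.266 and 0.126) and without the block (0.679, 0.25 and 0.145). The remaining lists did not pass, namely auxin transport, gibberellin metabolism, gibberellin perception, proton pumps, cytokinin, brassinosteroid, root hair, cell division, endodermis and phloem, with camera adjusted p between 0.0846 and 0.958. The gibberellin metabolism list had a median of -0.06 and a mean of 0.30.

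The second comparison asked what the antagonist does to basal expression. PEO-IAA lowered a few genes, Aux/IAA genes among them. IAA1 fell 7.99-fold, from 23.9 ± 2.96 to 2.98 ± 0.448 CPM (n = 3 each, log2 change -3.00, SE 0.32, edgeR adjusted p = 1.80e-04), and IAA2 fell 4.44-fold, from 108 ± 5.2 to 24.4 ± 6.33 CPM (-2.15, SE 0.19, adjusted p = 2.78e-05). AUF1, which codes for an auxin-induced F-box protein, fell 4.05-fold (-2.02, SE 0.29, adjusted p = 0.0114). AT3G42800 fell 3.69-fold (-1.88, SE 0.19, adjusted p = 9.50e-05) and AT1G27670 2.29-fold (-1.19, SE 0.20, adjusted p = 0.0391). The remaining called genes, AT3G51410 (-3.62) and AT2G22460 (-2.40), fell outside the naming rule and are named after their values were seen.

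With PEO-IAA 7 genes were lower, all by at least 2-fold, and 0 were higher in edgeR, where 152 genes were higher and 153 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and 21 lower. With the replicate block 11 were lower. The count of lower genes was 3, 3 and 4 without PEO-IAA replicate 1, 2 or 3. AUF1 lost its call without PEO-IAA replicate 1 or 2 (log2 change -2.19 to -1.84 over libraries left out), AT1G27670 without any PEO-IAA library or without mock replicate 1 or 3 (-1.31 to -1.10).

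The Aux/IAA list fell as a set (2 of 26 genes lower, 5 adjusted over the list alone, median -0.45, camera adjusted p = 1.16e-18, adjusted p = 0.0336 with an estimated correlation). So did SAUR genes (0 of 10 lower, 1 adjusted over the list alone, median -0.31, camera adjusted p = 8.74e-06, adjusted p = 0.0205 with an estimated correlation) and auxin-regulated transcription factors (0 of 17, 3 adjusted over the list alone, 2 with the replicate block, median -0.21, camera adjusted p = 1.47e-07, adjusted p = 0.0205 with an estimated correlation). With the block and an estimated correlation together these 3 calls were lost (adjusted p = 0.368 for Aux/IAA, 0.313 for SAUR genes and 0.0794 for transcription factors). Inactivation genes were lower (0 of 8, 3 adjusted over the list alone, median -0.60, camera adjusted p = 4.47e-07), which was lost at an adjusted p = 0.179 with an estimated correlation. Touch genes were higher than in mock (0 of 11, median 0.44, camera adjusted p = 0.00134), lost at an adjusted p = 0.398 with an estimated correlation. Auxin transport missed the threshold (median -0.03, camera adjusted p = 0.0515) and no other list passed. Biosynthesis had a median of 0.61 with a camera adjusted p of 0.353, and gibberellin metabolism a median of 0.03 with a mean of -0.16.

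IAA and PEO-IAA are related molecules given for the same time at doses of 10 nM and 10 µM, so the difference between them mixes compound and dose. They differed at auxin-induced genes. IAA1 was 27.6-fold higher with IAA than with PEO-IAA (log2 difference 4.78, SE 0.34, n = 3 each, edgeR adjusted p = 3.18e-07), IAA2 9.06-fold (3.18, SE 0.19, adjusted p = 9.63e-08) and GH3.1 17.5-fold (4.13, SE 0.36, adjusted p = 5.81e-06). GH3.2 differed 50-fold (115 ± 66.1 against 2.28 ± 1.86 CPM, SE 0.95, adjusted p = 0.0062). PID, a kinase gene that acts on PIN auxin carriers, was 12-fold higher with IAA (37.1 ± 7.37 against 3.08 ± 1.81 CPM, SE 0.51, adjusted p = 0.00117), and GATA23, a transcription factor gene of lateral root founder cells, 22.8-fold (SE 0.67, adjusted p = 0.00202). In the other direction, the auxin biosynthesis gene YUC8 was 3.89-fold lower with IAA (3.99 ± 0.719 against 15.6 ± 4.93 CPM, log2 difference -1.96, SE 0.30, adjusted p = 0.00235), with the mock at 8.51 ± 0.083 CPM. The expansin gene EXPA17 was 3.2-fold lower (40.3 ± 7.12 against 129 ± 40.5 CPM, -1.68, SE 0.33, adjusted p = 0.0203), with the mock at 83.2 ± 9.81 CPM.

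In this direct comparison 99 genes were higher and 26 lower with IAA, 72 and 16 by at least 2-fold. With the replicate block they were 234 and 107, and all 125 calls were kept. Other named genes higher with IAA were IAA5 (log2 difference 6.94, SE 1.1), SAUR68 (5.90, SE 1.04), AT3G51410 (4.66, SE 0.55), GA2OX8 (4.33, SE 0.77), which codes for a gibberellin-inactivating oxidase, TCH3 (2.63, SE 0.56), ACS11 (2.42, SE 0.32), GH3.5 (2.31, SE 0.27), HAT2 (1.95, SE 0.17), ARF19 (1.74, SE 0.22), IAA4 (1.65, SE 0.17) and HSFB2A (1.25, SE 0.24). SAUR24 was at least 25.3-fold higher, with 80 against 0 counts, and SAUR26 had a ratio of 51.3 (8.83 to 2060). Other genes lower with IAA were AT2G43890 (-2.94, SE 0.56), AT1G61840 (-2.68, SE 0.58), AT1G05650 (-2.17, SE 0.39) and AT4G34810 (-1.76, SE 0.26). The higher count was 53 and 40 without PEO-IAA replicates 1 and 3 and 61 without IAA replicate 3. The lower count was 17, 16 and 13 without IAA replicates 1, 2 and 3 and 14 and 10 without PEO-IAA replicates 1 and 3.

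Of the 24 named and called genes, 14 kept their call without any 1 library, among them IAA5, whose log2 difference was 6.35 without PEO-IAA replicate 2. SAUR68 lost it only without PEO-IAA replicate 1 (log2 difference 5.34, adjusted p = 0.0598), stood at 5.31 without PEO-IAA replicate 2, and without PEO-IAA replicate 3, which held all of its PEO-IAA counts, it was at least 74.8-fold higher. GH3.2 lost it only without PEO-IAA replicate 3 (5.09 to 6.15 over libraries left out) and GA2OX8 without any PEO-IAA library (4.03 to 4.70). SAUR24 (at least 16.2-fold to at least 28.1-fold higher) and TCH3 (2.46 to 2.96) lost it without any of the 6 libraries, and EXPA17 (-1.89 to -1.43) and AT1G61840 (-4.11 without IAA replicate 2, -2.27 at the other end) without all but 1 of them. AT2G43890 (-3.29 to -2.54) lost it without PEO-IAA replicate 1 or 3 or IAA replicate 2 or 3, AT1G05650 (-2.46 to -1.78) without PEO-IAA replicate 1 or IAA replicate 2 or 3, and HSFB2A (1.1 to 1.5) without PEO-IAA replicate 2 or 3 or IAA replicate 3. These fits did not use the replicate block. With the block and all libraries, the edgeR adjusted p was 1.89e-04 for TCH3 and 0.0381 for SAUR24.

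Of 26 Aux/IAA genes 9 were higher with IAA and 0 lower (11 and 0 adjusted over the list alone, median 0.70, camera adjusted p = 6.11e-34, adjusted p = 0.00314 with an estimated correlation), including IAA19 (2.70), IAA6 (3.84) and IAA13 (1.46). Inactivation genes gave 4 of 8 (5 adjusted over the list alone, median 1.99, camera adjusted p = 1.94e-17, adjusted p = 0.00921 with an estimated correlation), transcription factors 4 of 17 (7 adjusted over the list alone, median 0.80, camera adjusted p = 4.60e-14, adjusted p = 0.00133 with an estimated correlation), and SAUR genes 2 of 10 (3 adjusted over the list alone, median 0.30, camera adjusted p = 1.21e-11, adjusted p = 8.65e-04 with an estimated correlation). With the block and an estimated correlation together the Aux/IAA call was lost (adjusted p = 0.104), and the inactivation, SAUR and transcription factor lists passed (0.0486, 0.0486 and 0.0213). Auxin transport held 2 higher genes of 16, PID and PIN3 (0.58), 3 adjusted over the list alone, without passing as a set (camera adjusted p = 0.0537).

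The biosynthesis list was lower with IAA (1 of 7, median -0.26, camera adjusted p = 0.0113, adjusted p = 0.0798 with an estimated correlation). Over that list alone 1 gene was higher and 3 were lower. The expansins (1 of 18 lower, median -0.09, camera adjusted p = 0.0166) lost their call with an estimated correlation (adjusted p = 0.231) and with the block (0.0577, with 2 genes lower). Root hair genes (median -0.18, camera adjusted p = 0.0253) had an adjusted p = 0.503 with an estimated correlation. The endodermis list passed only with the block (median -0.14, camera adjusted p = 0.0118, 0.0537 without it) and lost its call with an estimated correlation (adjusted p = 0.438 with the block and 0.503 without it). Of 16 receptor and ARF genes 1 was lower only with the block. No other list passed. Not every auxin signalling gene told the treatments apart. The 95% intervals of the log2 difference were -0.16 to 0.18 for IAA7, -0.15 to 0.48 for IAA8, -0.43 to 0.28 for ARF7 and -0.66 to 0.88 for AXR3.

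Both treatments were compared with the same mock libraries. Across 19809 genes, which are not independent replicates, the covariance of their log2 changes was 0.0113 (r 0.15). In 100 simulations of unchanged groups against that mock it was 0.0183 (0.0172 to 0.0200, r 0.507) with the spread left after fitting the replicate block. With the spread of a fit without the block, which still holds the differences between replicate numbers, it was 0.0608 (0.0558 to 0.0671). Genes higher with IAA and lower with PEO-IAA numbered 4, namely IAA1, IAA2, AUF1 and AT3G42800, where independent lists would share 0.01. The mock was not split. Chance values of a shared mock move both changes the same way, as in the simulations, so they work against an overlap in opposite directions.

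**Figure D2:**
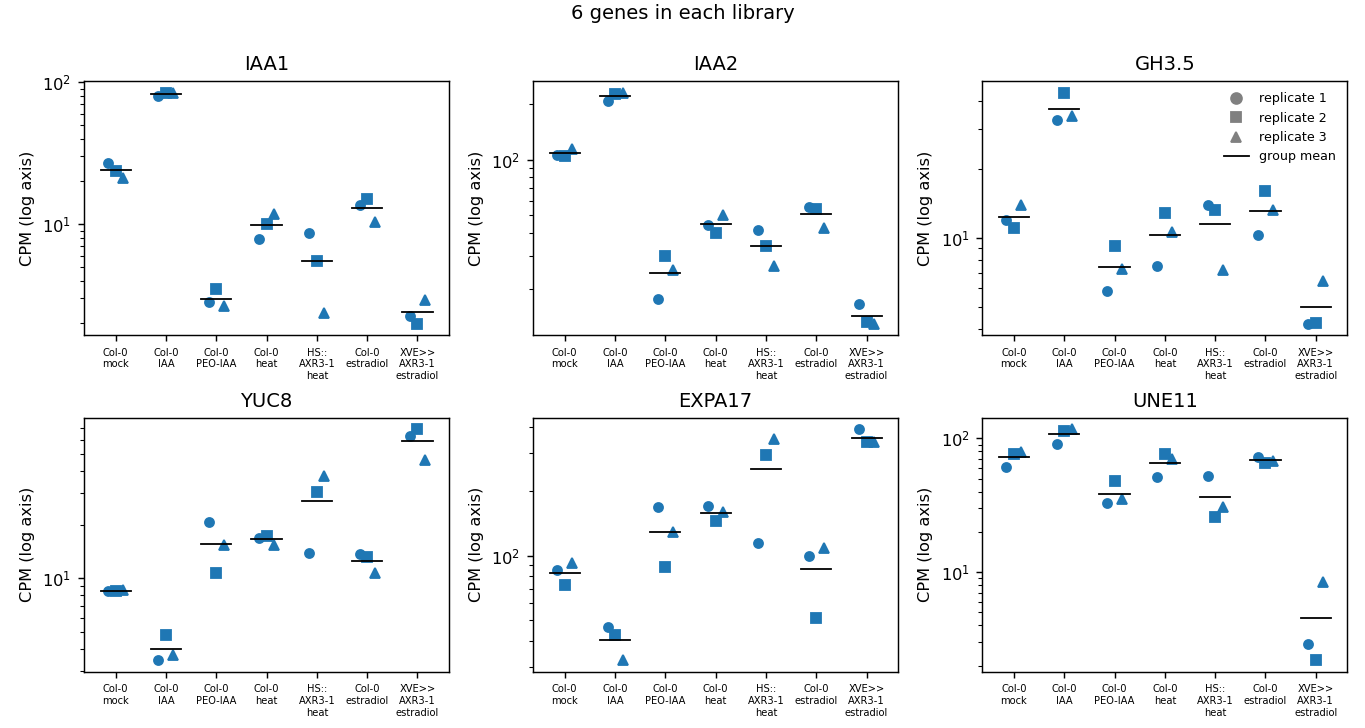
Level of IAA1, IAA2, GH3.5, YUC8, EXPA17 and UNE11 in CPM (log axis) in each of the 21 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. IAA1 and IAA2 sit highest with IAA (means 82.5 and 221 CPM) and low with PEO-IAA (2.98 and 24.4), while UNE11 is at 4.53 CPM in XVE>>AXR3-1 and 68.6 in its Col-0.

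The estradiol experiment asked which genes differ from Col-0 in XVE>>AXR3-1 after 2 h of estradiol. Neither AXR3-1 line had uninduced libraries, so a response to AXR3-1 and a fixed difference of the line cannot be told apart. Of 26 Aux/IAA genes 12 fell, and of 7 auxin biosynthesis genes YUC5 and YUC8 rose while TAA1 fell. Neither list held its call as a set with an estimated correlation (adjusted p = 0.0569 for both). IAA16 fell 5.41-fold in XVE>>AXR3-1, from 319 ± 11.4 to 59 ± 31.2 CPM (n = 3 each, log2 change -2.43, SE 0.36, edgeR adjusted p = 9.57e-04), IAA1 5.41-fold (-2.44, SE 0.32, adjusted p = 4.34e-04) and IAA2 3.56-fold to 14.3 ± 1.97 CPM (-1.83, SE 0.19, adjusted p = 8.56e-05). RSL4, a regulator of root hair growth, fell 5.03-fold (-2.33, SE 0.40, adjusted p = 0.00338). YUC8 rose from 12.5 ± 1.57 to 59.3 ± 11.8 CPM (2.24, SE 0.29, adjusted p = 3.28e-04) and YUC5 8.34-fold (3.06, SE 0.70, adjusted p = 0.0205), whereas TAA1, which acts one step before them, fell 3.77-fold (-1.91, SE 0.21, adjusted p = 1.25e-04). EXPA17 rose 4.13-fold from 86.1 ± 30.7 to 355 ± 28.7 CPM (2.04, SE 0.34, adjusted p = 0.00212).

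In all, 290 genes were higher and 266 lower, and with the replicate block 828 and 661. Among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, the largest rises were AT1G28160 (log2 change 5.75, SE 1.15), AT3G26490 (4.06, SE 0.43), CYP71A12 (4.04, SE 0.91), ATPMEPCRB (3.41, SE 0.72) and YUC5, and the largest falls UNE11 (-3.90, SE 0.39, from 68.6 ± 3.92 to 4.53 ± 3.46 CPM), AT4G01110 (-3.62, SE 0.54), AT5G24880 (-3.35, SE 0.57), AT4G35200 (-3.29, SE 0.54) and AT5G45580 (-3.10, SE 0.45). Below that level larger changes were called, such as a fall of AT2G22460 (-4.09). The higher count was 130 without XVE>>AXR3-1 replicate 1 and 106 and 161 without Col-0 replicates 2 and 3. The lower count was 138 and 151 without XVE>>AXR3-1 replicates 1 and 2 and 167 and 173 without Col-0 replicates 2 and 3. Of 26 named and called genes 19 kept their call without any 1 library. The folds of 3 of these moved by over 1.5 times without XVE>>AXR3-1 replicate 3, to log2 changes of -4.76 for UNE11, -4.40 for AT4G01110 and -4.30 for AT5G24880. BRN2 (-1.12 to -1.06) and GH3.5 (-1.64 to -1.23) lost their call without XVE>>AXR3-1 replicate 1, AT1G28160 without Col-0 replicate 2 (5.15, adjusted p = 0.0502), and ATPMEPCRB (3.11 to 3.75) without Col-0 replicate 2 or 3. CYP71A12 (3.55 to 4.28) lost it without XVE>>AXR3-1 replicate 1 or any Col-0 library, YUC5 (2.82 to 3.77, the latter without Col-0 replicate 1) without XVE>>AXR3-1 replicate 1 or 2 or Col-0 replicate 2 or 3, and NPF3.1 (1.56 to 2.22) without XVE>>AXR3-1 replicate 1 or Col-0 replicate 1 or 3. All Col-0 counts of AT1G28160 lay in replicate 1, without which the gene was at least 306-fold higher. The fits with a library left out did not use the replicate block. With the block and all libraries, the edgeR adjusted p was 2.06e-04 for CYP71A12 and 0.00579 for YUC5.

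Among the auxin lists, 12 of 26 Aux/IAA genes fell and 0 rose, against 16 and 2 adjusted over the list alone (median -0.94, camera adjusted p = 1.60e-16), with IAA10 (-1.51), IAA13 (-1.40) and IAA14 (-1.26) as further examples. With the block 13 fell and 1 rose. The call was lost at an adjusted p = 0.0569 with an estimated correlation, while fry gave an adjusted p of 0.00283. Of 8 inactivation genes 1 fell, GH3.5 (-1.40, SE 0.27), 5 adjusted over the list alone and 5 with the block (median -1.14, camera adjusted p = 1.06e-05, adjusted p = 0.17 with an estimated correlation). GH3.3 had 2 counts in the line and 86 in Col-0, a ratio of 38.7 (10.4 to 325). None of 17 transcription factors fell alone, 2 did adjusted over the list alone and 4 with the block (median -0.60, camera adjusted p = 2.80e-04, adjusted p = 0.0986 with an estimated correlation). No SAUR gene of 10 passed, 1 rose and 1 fell with the block, and the set had a median of -0.70, or -0.57 with genes at their bounds (camera adjusted p = 0.0304, adjusted p = 0.17 with an estimated correlation). Auxin biosynthesis rose as a set (YUC5 and YUC8 higher and TAA1 lower of 7, 4 and 1 adjusted over the list alone and with the block, median 2.00, camera adjusted p = 0.00171, adjusted p = 0.0569 with an estimated correlation). Of 16 receptors and ARFs 3 fell, ARF10 (-1.16, SE 0.17), ARF16 (-1.41) and AFB1 (-0.57), with a median of -0.11 (camera adjusted p = 0.0103, adjusted p = 0.392 with an estimated correlation). Of 16 transport genes PIN3 (-0.66, SE 0.11) and PIN7 (-0.88) fell, and the set did not pass (median -0.02, camera adjusted p = 0.241).

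Of 11 root hair genes 6 fell in XVE>>AXR3-1 and 0 rose (7 and 0 adjusted over the list alone), namely RSL4, EXPA7 (-1.81), EXPA18 (-1.44), RHD6 (-1.37), RSL2 (-0.94) and COBL9 (-0.71). The median was -0.98 (camera adjusted p = 3.32e-11), lost at an adjusted p = 0.0569 with an estimated correlation. The touch, wounding and jasmonate list was higher (1 of 11, WRKY33 at 1.47 with SE 0.28, 2 adjusted over the list alone and with the block, median 0.85, camera adjusted p = 1.57e-04, adjusted p = 0.17 with an estimated correlation). Its mean log2 CPM was 3.25, 3.24 and 3.4 in XVE>>AXR3-1 and 2.39, 2.21 and 2.61 in its Col-0. In the ethylene list ACS7 (2.53), ACS6 (1.29) and ACO4 (1.08) rose while ACS2 (-2.58, SE 0.32) and ACS11 (-3.26) fell, 5 and 2 of 16 adjusted over the list alone (median 0.34, camera adjusted p = 0.0407, adjusted p = 0.542 with an estimated correlation). These genes code for enzymes of ethylene synthesis.

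Neither gibberellin list passed as a set in the main fit. The metabolism list holds biosynthetic and inactivating enzymes, and the other list holds receptors and repressors. A signed test of such mixed lists cannot show that the pathway was unchanged. GA3OX1, which makes bioactive gibberellin, fell 2.75-fold (from 12.5 ± 2.1 to 4.52 ± 1.56 CPM, -1.46, SE 0.26, edgeR adjusted p = 0.00439) as 1 of 13 metabolism genes, and with the block 1 rose and 2 fell (median 0.02 with a mean of -0.07, camera adjusted p = 0.169). NPF3.1, a gibberellin transporter gene, rose 3.34-fold (1.74, SE 0.37, adjusted p = 0.0119) as 1 of 15 perception and response genes, and that list passed only with the block (median 0.16, camera adjusted p = 0.0382, 0.111 without it), a call lost with an estimated correlation (adjusted p = 0.194 with the block and 0.19 without it). EXPA17 was the 1 higher gene of 18 expansins, and with the block 2 rose and 2 fell (median -0.06 with a mean of 0.13, camera adjusted p = 0.461). No XTH gene of 23 passed, 2 rose and 5 fell adjusted over the list alone and 2 and 4 with the block (camera adjusted p = 0.218). No proton pump gene of 5 passed, and 2 fell with the block (adjusted p = 0.205). Of 13 brassinosteroid genes BZR1 (-0.76, SE 0.13) and BAS1 (-1.40) fell, and with the block 2 rose and 4 fell (median 0.07, mean -0.18, camera adjusted p = 0.417). Of 3 root cap genes BRN1 (0.75) rose and BRN2 (-1.10, SE 0.22) fell, and with the block 1 rose and 2 fell (camera adjusted p = 0.458). Cytokinin genes (18, of which 2 rose and 1 fell with the block, camera adjusted p = 0.966), heat shock genes (26, 0.966), cell division genes (18, 0.736), endodermis (9, of which 1 fell with the block, 0.892), xylem (7, 0.966), phloem (6, 0.966), non-hair epidermis (2, of which 1 fell with the block, 0.254) and green tissue (4, of which 1 rose with the block, median 0.35 with a mean of -0.22, 0.695) did not pass as sets.

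**Figure D3:**
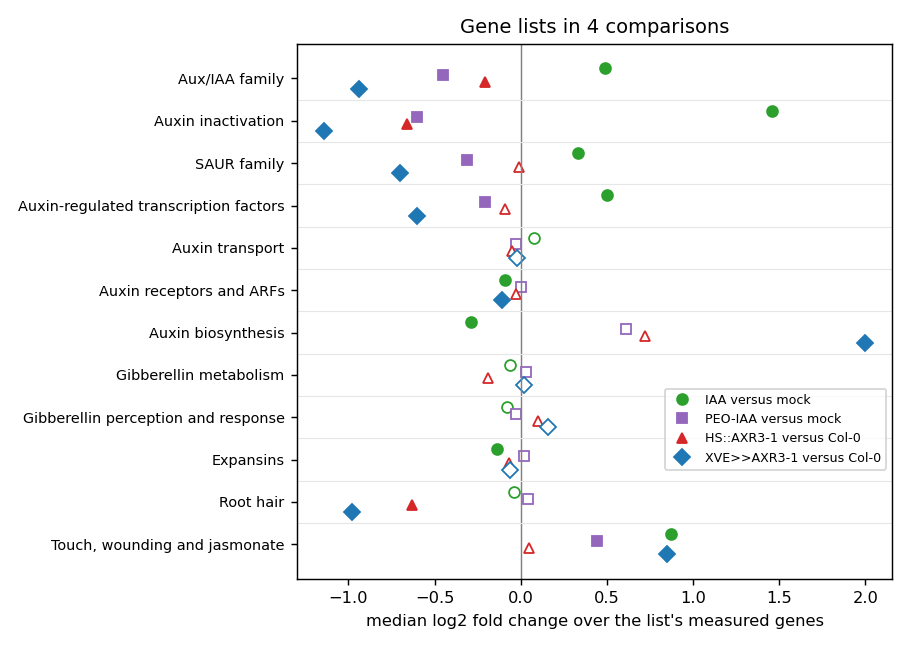
Median log2 change of 12 gene lists (horizontal axis) in 4 comparisons, filled where the camera adjusted p was under 0.05 and open where not. Aux/IAA genes lie at 0.49 with IAA, -0.45 with PEO-IAA and -0.94 in XVE>>AXR3-1, and auxin biosynthesis at 2.00 in XVE>>AXR3-1.

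In the heat experiment the question was the same for HS::AXR3-1, with 80 min of recovery after the heat. MRD1 was 104-fold higher in the line than in heat-shocked Col-0 (64.9 ± 5.97 against 0.63 ± 0.637 CPM, n = 3 each, log2 change 6.69, SE 0.81, edgeR adjusted p = 0.00382). Its level did not follow that of AXR3, at 71.4, 59.7 and 63.5 CPM where AXR3 held 181, 298 and 861. In XVE>>AXR3-1 MRD1 stood at 0.438 ± 0.369 CPM, so its difference need not be a response to AXR3-1. AT5G26270 was 3.79-fold higher (1.92, SE 0.30, adjusted p = 0.0375), AT2G40095 1.93-fold (0.95, SE 0.15, adjusted p = 0.0375), AT5G50630 1.8-fold (0.85, SE 0.12, adjusted p = 0.0137) and AT5G18460 1.66-fold (0.73, SE 0.12, adjusted p = 0.0382). These 5 genes were all the calls, and no auxin list member was among them. In the main edgeR fit 0 genes were lower, with 518 higher and 320 lower at an unadjusted p under 0.05, and DESeq2 called 26 and 14.

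The libraries of this line differed in their heat response. The mean log2 CPM of the 26 heat shock genes was 2.89, 6.04 and 7.96 in HS::AXR3-1 replicates 1, 2 and 3 and 6.40, 6.48 and 7.24 in heat-shocked Col-0, against 0.97 to 2.50 in the 15 unheated libraries. The order of the 3 libraries was that of their AXR3 level. The count of higher genes was 9, 3 and 13 without replicate 1, 2 or 3 of the line and 1, 1 and 0 without replicate 1, 2 or 3 of Col-0. The count of lower genes was 11 without replicate 1 and 2 without replicate 3 of the line. In splits of the 6 libraries of this experiment, counted after the results were seen, another grouping gave 672 calls. None of the 5 genes kept its call without each library in turn. MRD1 lost it only without Col-0 replicate 3 (7.82 without Col-0 replicate 1 and 6.07 without Col-0 replicate 2) and AT5G50630 only without a Col-0 library (0.71 to 0.96). AT5G26270 (1.68 to 2.12) kept it only without replicate 3 of the line, and AT2G40095 (0.87 to 1.09) and AT5G18460 (0.69 to 0.78) only without replicate 1.

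**Figure D4:**
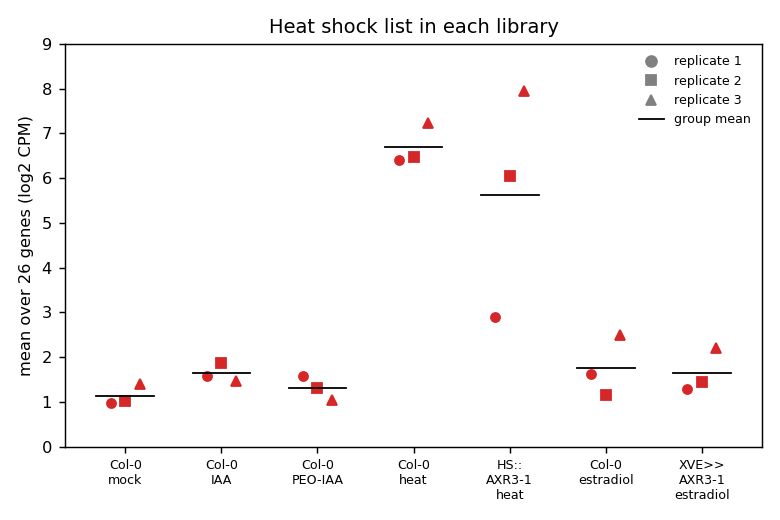
Mean log2 CPM of the 26 heat shock genes in each of the 21 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. HS::AXR3-1 replicate 1 sits at 2.89, the other heated libraries between 6.04 and 7.96, and the unheated ones between 0.97 and 2.50.

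As sets, root hair genes were lower in HS::AXR3-1 (0 of 11 called, 3 lower adjusted over the list alone, median -0.63, camera adjusted p = 6.72e-07, adjusted p = 0.48 with an estimated correlation). Their mean log2 CPM was 5.30, 4.93 and 4.63 in the line and 5.47, 5.37 and 5.76 in Col-0, and the median was -0.94, -0.55 and -0.34 without replicate 1, 2 or 3 of the line. Aux/IAA genes were lower too (0 of 26 called, 1 lower adjusted over the list alone, median -0.21, camera adjusted p = 1.01e-05, adjusted p = 0.681 with an estimated correlation), with means of 3.57, 3.44 and 2.86 in the line and 3.39, 3.70 and 3.87 in Col-0. In both lists the library with the weak heat response, replicate 1, held the highest mean of the line. Inactivation genes (8, median -0.66, camera adjusted p = 0.0258, adjusted p = 0.73 with an estimated correlation) and cytokinin genes (18, -0.30, 0.0281 and 0.797) were lower, and endodermis genes (all 9 above 0, median 0.21, 0.017 and 0.681) were higher. Lists were also tested without replicate 1 or 3 of the line, settings added after seeing the data. Without replicate 3 the calls of the Aux/IAA (camera adjusted p = 0.507), inactivation (0.865), cytokinin (0.929, median -0.00) and endodermis lists (0.188) were lost. Without replicate 1 these 4 lists passed with the preset correlation but not with an estimated one (adjusted p = 0.102, 0.461, 0.505 and 0.461 in the same order), and the Aux/IAA median was -0.36 over the 27 genes then measured. The root hair list passed in both settings with the preset correlation (2.23e-10 without replicate 1 and 0.0183 without replicate 3) and in neither with an estimated one (adjusted p = 0.102 and 0.964). The heat shock list had a median of 0.12 and a mean of 0.15 while camera gave the opposite direction (adjusted p = 2.10e-05, adjusted p = 0.73 with an estimated correlation). Without HS::AXR3-1 replicate 1 its median was 0.58 and the direction upward (adjusted p = 0.131), and without replicate 3 the median was -1.44.

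The remaining lists did not pass in HS::AXR3-1 with all libraries. Without replicate 3 of the line the cell division list was higher (median 0.33, camera adjusted p = 3.22e-06), a call lost with an estimated correlation (adjusted p = 0.894). Without replicate 1 auxin biosynthesis was higher (median 1.04, camera adjusted p = 0.00545) and the XTH (-0.10, 0.0184) and root cap lists (-0.48, 0.0401) were lower. These calls were lost with an estimated correlation as well (adjusted p = 0.102, 0.461 and 0.264). With all libraries, receptors and ARFs had a camera adjusted p of 0.0575 and 2 lower genes adjusted over the list alone, auxin biosynthesis 0.161 with a median of 0.72 and 1 lower gene adjusted over the list alone, and transcription factors 0.161 with 1 lower. The gibberellin lists gave 0.737 for metabolism and 0.521 for perception and response. SAUR, transport, expansin, XTH, proton pump, ethylene, brassinosteroid, touch, cell division, xylem, phloem, root cap, non-hair epidermis and green tissue lists had camera adjusted p between 0.29 and 1.

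The effects of both lines, which differ in the tag and the inducing treatment as well, were compared directly. The difference passed for 5 genes, 3 with a higher and 2 with a lower value in HS::AXR3-1 than in XVE>>AXR3-1, and AXR3 itself did not pass (log2 difference -0.82, SE 0.52, edgeR adjusted p = 1). AXR3 passed without HS::AXR3-1 replicate 3 (-1.72, adjusted p = 0.0313), and over the other settings its adjusted p was 0.324 to 1, with log2 differences from -1.09 to -0.45. The higher count was 0 without replicate 1 of HS::AXR3-1, without any heat-shocked Col-0 library, without XVE>>AXR3-1 replicate 1 or 2 or without estradiol Col-0 replicate 2, and it was 1 without estradiol Col-0 replicate 1, 29 without HS::AXR3-1 replicate 3 and 6 without XVE>>AXR3-1 replicate 3. The lower count was 7 without HS::AXR3-1 replicate 3. It was 1 without heat-shocked Col-0 replicate 2, estradiol Col-0 replicate 1 or XVE>>AXR3-1 replicate 3, and 0 without HS::AXR3-1 replicate 1, heat-shocked Col-0 replicate 1 or 3, XVE>>AXR3-1 replicate 1 or 2 or estradiol Col-0 replicate 2 or 3. As a set Aux/IAA genes were less reduced in HS::AXR3-1 (median difference 0.70, 4 higher adjusted over the list alone, camera adjusted p = 1.02e-08), lost at an adjusted p = 0.498 with an estimated correlation. Root hair genes differed by a median of 0.38 (camera adjusted p = 0.00201, adjusted p = 0.498 with an estimated correlation) and touch genes by -1.06 (0.00867 and 0.498). The same call and loss held for the inactivation (median 0.60, 0.0145 and 0.517), SAUR (0.58, 0.0317 and 0.498), transcription factor (0.43, 0.0319 and 0.498), ethylene (-0.38, 0.028 and 0.532) and endodermis lists (0.23, 0.0351 and 0.517). The heat shock list had a median difference of 0.24 with a camera direction below 0 (0.0041 and 0.633).

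Genes called higher in both lines numbered 3, AT2G40095, AT5G18460 and AT5G26270, where 0.0732 would be shared by independent lists (one-sided Fisher's exact test p = 3.04e-05), and 0 were lower in both, since the main edgeR fit called none lower in HS::AXR3-1. Both lists came from 1 fit with 1 estimate of the spread per gene, so they are not independent and the Fisher p is only a rough guide. In fits of each experiment alone, with the length offset or without the low-count filter, 0 were shared. With DESeq2 18 were shared higher and 12 lower. With the replicate block, whose numbers do not pair the libraries of the heat experiment, 48 and 18 were shared. Without HS::AXR3-1 replicate 1, 7 of 9 higher and 11 of 11 lower genes of the line were shared. Without replicate 2 these were 0 of 3 and 0 of 0, and without replicate 3 2 of 13 and 0 of 2. Of the genes called higher in XVE>>AXR3-1, leaving out AXR3, 268 of 289 (92.7%) lay above 0 in HS::AXR3-1, with a median log2 change of 0.34 there and 1.02 in XVE>>AXR3-1 (camera with an estimated correlation p = 1.83e-04). Of those called lower 241 of 266 (90.6%) lay below 0, with medians of -0.38 and -1.41 (camera with an estimated correlation p = 0.00418). The XVE>>AXR3-1 libraries chose these genes, which tends to enlarge the medians there. The medians of both lines therefore do not measure how much weaker the effect was in HS::AXR3-1. The median of these lower genes in HS::AXR3-1 was -0.60 without replicate 1 of the line and -0.25 without replicate 3. Across all 19809 genes, which are not independent replicates, the log2 changes of both lines had a Pearson r of 0.316 and a Spearman rho of 0.272.

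Genes that responded to IAA were then followed in the lines. The 29 genes higher with IAA had a median log2 change of -0.07 with PEO-IAA, where 20 lay below 0 and 4 were called lower (camera with an estimated correlation p = 0.00138). With the 111 genes higher in the replicate block fit this call was lost, with 55 below and 56 above 0 and a median of 0.01 (p = 0.161 with an estimated correlation), while the 19 genes that rose at least 2-fold had a median of -0.73 (p = 2.52e-05 with an estimated correlation). In simulations of unchanged groups against the same mock, the 29 genes with the largest simulated rise had a median of 0.68 with the spread left after fitting the replicate block. With the spread of a fit without the block it was 1.35. Those genes were chosen by fold and not by adjusted p, so these medians are only a rough guide for the real set. In XVE>>AXR3-1 the 29 genes higher with IAA split, with 3 called higher and 6 lower (median 0.22, 19 above 0, p = 0.884 with an estimated correlation). The 19 that rose at least 2-fold split there as well, with 10 below and 9 above 0, and with 3 called higher and 6 lower. Their median was -0.56 (camera with the preset correlation p = 0.00454, p = 0.133 with an estimated one). In HS::AXR3-1 0 of the 29 were called in edgeR (median -0.00, camera p = 0.037, p = 0.318 with an estimated correlation). The 4 genes lower with IAA lay above 0 in HS::AXR3-1 (4 of 4, median 0.35, p = 7.16e-04 with an estimated correlation), and 3 of them were called higher in XVE>>AXR3-1 (median 0.59, p = 3.29e-04 with an estimated correlation). With PEO-IAA their median was 0.21 (p = 0.0437 with an estimated correlation), and that of the 22 genes lower in the replicate block fit was 0.03 (p = 0.49 with an estimated correlation).

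The heat treatment itself was visible in Col-0. HSP17.6II stood at 2180 ± 429 CPM in heat-shocked and 1.14 ± 0.756 CPM in estradiol-treated Col-0 (n = 3 each, log2 difference 10.89, SE 1.01, edgeR adjusted p = 4.01e-05), and HSP18.2 at 2900 ± 376 and 0.991 ± 0.378 CPM (11.50, SE 1.41, adjusted p = 5.29e-04). HSP17.4 (8.83, SE 0.91) and HSP17.6C (9.08, SE 0.98) rose as well, and HSP21 was at least 144-fold higher. Of 26 heat shock genes 14 rose and 0 fell (18 and 0 adjusted over the list alone, median 4.20, camera adjusted p = 4.53e-24). With an estimated correlation the adjusted p = 0.225, and fry gave an adjusted p of 0.00131. In all, 170 genes were higher and 136 lower, in a comparison where the treatment and the experiment cannot be told apart. The higher count was 74, 45 and 74 without heat-shocked replicates 1, 2 and 3 and 40, 31 and 37 without the estradiol ones, and the lower count 46, 33 and 68 and 35, 42 and 35. All 4 named genes kept their call without any 1 library, with HSP17.6II at 11.60 without estradiol Col-0 replicate 3.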

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

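The 5 genes below differed between the effects of the lines in a planned test. The tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

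For 5 genes the change against Col-0 differed between HS::AXR3-1 and XVE>>AXR3-1 by a test of the difference itself. ACS11, an ACC synthase gene, had a log2 difference of 3.74 (SE 0.54, edgeR adjusted p = 0.0329), with a log2 change of 0.48 in HS::AXR3-1 and -3.26 in XVE>>AXR3-1. AT2G22460 differed by 3.59 (SE 0.56, adjusted p = 0.0389, -0.50 and -4.09) and UNE11 by 3.06 (SE 0.50, adjusted p = 0.0389, -0.85 and -3.90). AT1G19380 differed by -2.90 (SE 0.43, adjusted p = 0.0329, -0.41 and 2.49) and AT2G47550 by -1.80 (SE 0.29, adjusted p = 0.0389, -0.06 and 1.74). None of the 5 was called in HS::AXR3-1 (adjusted p = 1 for each). The naming rule covers UNE11, AT1G19380 and AT2G47550, and the other ones are named after their values were seen. Without 1 library, UNE11 (2.69 to 3.91, the latter without XVE>>AXR3-1 replicate 3) kept its call only without HS::AXR3-1 replicate 2 or 3 or XVE>>AXR3-1 replicate 3, and AT2G47550 (-2.16 to -1.63) only without HS::AXR3-1 replicate 2 or 3. AT1G19380 (-3.24 to -2.65) kept it only without a library named for UNE11, heat-shocked Col-0 replicate 2 or estradiol Col-0 replicate 1. Of 40 splits of the 12 libraries, the real one included, 6 gave as many genes as the real 5, and the highest of the others gave 132. A split that mixes the libraries of 1 line can count the effect of the other line as a difference. These splits therefore cannot decide, and chance was not excluded.

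HS::AXR3-1 replicate 1 had a weak heat response, with a mean of 2.89 log2 CPM over the heat shock list where the other heated libraries had 6.04 to 7.96. A library of another line is argued against by MRD1, which was 56 times higher there than in the highest of the 18 libraries of other groups. Unheated plants are argued against by 5 heat shock genes at over 10 times the highest unheated library, such as HSP17.6II at 107 CPM against 2.01, although a first form of this test, counting genes above the highest other unheated library, did not decide (9 of 26 there and 12 in estradiol Col-0 replicate 3), and the 10-fold bound was set after the ratios were seen. Reads carried over from the other heated libraries are argued against because HSP17.6II needs a share 3.78 times the largest one that HSP18.2 allows (3.48% against 0.919%), and the library's total of 21.68 M reads was not the lowest of the heated ones. A milder or later heat response of these plants may remain, which no label of this series describes and which was not tested.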

How the results depend on the processing

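Of the values computed under alternative settings, 1861 were counted as the same, 354 kept the direction and lost the call, 19 gained it, 116 counts or levels moved and 4 reversed. For a count of calls, the same means within 1.5 times. For a gene or list it means the same side of the threshold, and the direction could differ where neither value passed. Lists without 1 HS::AXR3-1 library, and lists with the block and an estimated correlation together, were added after seeing the data, and the other settings were planned. Median-of-ratios scaling and robust estimation moved no count of calls by over 1.5 times. Where counts fell without 1 library or in a fit of 1 experiment, fewer samples entered the fit, and for the other changes the cause was not tested.

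DESeq2 called more genes throughout, with 96 higher and 20 lower for IAA, 2 and 21 for PEO-IAA, 174 and 67 for IAA against PEO-IAA, 26 and 14 for HS::AXR3-1, 476 and 401 for XVE>>AXR3-1, 45 and 12 for the difference between the lines, 507 and 466 for the heat check, and 18 and 12 shared by the lines. Fits of 1 experiment gave 11 and 0 for IAA, 0 higher for HS::AXR3-1 (edgeR), 0 and 0 for the difference, 30 and 22 for the heat check and 0 shared higher. The length offset gave 2 lower for IAA, 1 higher for PEO-IAA, 1 higher for HS::AXR3-1, 6 higher for the difference and 0 shared higher. Without the low-count filter HS::AXR3-1 had 2 higher and 0 were shared.

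With the replicate block the counts were 111 and 22 for IAA, 11 lower for PEO-IAA, 234 and 107 for IAA against PEO-IAA and 828 and 661 for XVE>>AXR3-1. Besides the calls given with the comparisons, the block with the preset correlation changed no other call of a named gene or list test in these paired experiments. Where the numbers do not pair the libraries (r 0.09 to 0.45 in the heat experiment, 4 of 6 libraries closest to their own number), it gave 63 and 23 for HS::AXR3-1, 31 and 20 for the difference, and 48 and 18 shared. The block fit gave 327 lower for the heat check, whose groups belong to different experiments. There it compares levels fitted for replicate 1 and not group means, so this count is no repeat of the check.

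Leaving out 1 library gave 6 to 14 higher and 0 to 2 lower for IAA and 3 to 6 lower for PEO-IAA. It gave 40 to 78 and 10 to 28 for IAA against PEO-IAA, 0 to 13 and 0 to 11 for HS::AXR3-1, 106 to 217 and 138 to 311 for XVE>>AXR3-1, 0 to 29 and 0 to 7 for the difference, and 31 to 74 and 33 to 68 for the heat check.

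The set of genes higher with IAA reached p = 0.318 with an estimated correlation in HS::AXR3-1, and its median there turned to 0.06 with sets from the block fit. In XVE>>AXR3-1 that set had a median of 0.22, 0.27 with sets from the block fit and -0.56 with genes changed at least 2-fold (camera with the preset correlation p = 8.63e-06 and p = 0.00454 for the latter sets, lost at p = 0.142 and p = 0.133 with an estimated correlation). The sign of the median reversed in the last set, although its genes were split, with 10 below and 9 above 0. With PEO-IAA its median turned to 0.01 with sets from the block fit (p = 0.161 with an estimated correlation). The set lower with IAA had 0.03 with PEO-IAA with sets from the block fit (camera with the preset correlation p = 0.105). The heat shock list in HS::AXR3-1 reversed without replicate 1 (camera adjusted p = 0.131, adjusted p = 0.909 with an estimated correlation) and kept its direction without replicate 3 (2.29e-15). At this depth and n the simulated fits recovered 17.9% and 14.9% of 1.5-fold changes, so smaller effects were mostly not detectable.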

Other observations

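All tests in this part, the splits of the libraries included, were chosen after the results were seen.

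Most of the genes that rose with IAA belong to no auxin list. These 21 genes include MPK3, the calcium-dependent kinase genes CPK28 and CPK32, the syntaxin gene SYP121 and the transcription factor gene NAC062, and their median log2 change was 1.05 with IAA. Handling shared by both chemical treatments is argued against as the whole cause by their median with PEO-IAA, -0.02 (quartiles -0.11 and 0.11), although AT1G59312 stood at 5.20 with IAA and 5.17 with PEO-IAA and the touch list was higher with both chemicals (with PEO-IAA 10 of 11 above 0, median 0.44, camera adjusted p = 0.00134, adjusted p = 0.398 with an estimated correlation). A single odd IAA library is argued against as the whole cause, since 9, 9 and 8 of the 21 genes were called again without IAA replicate 1, 2 or 3. However, only 1, 6 and 1 were called without both the IAA and the mock library of replicate 1, 2 or 3. In each IAA library all 21 lay above every mock library (lowest of the 3 median changes 0.91, with a lower quartile of 0.77). These same libraries chose the genes, so that is close to fixed in advance and is no test. Single genes differed, as AUF1 (-2.02) and AT3G42800 (-1.88) were called lower with PEO-IAA. In XVE>>AXR3-1 AUF1 (-1.86) and AT1G60010 (-0.89) were called lower. All the remaining genes of the 21 lay above 0 there, with NUDT7 (0.93), NAC062 (0.62) and AT4G34150 (0.71) called higher. A response to auxin stays open for the 21 genes as a set, and handling of the IAA plants alone was not tested.

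Fewer genes were called in HS::AXR3-1 (5) than in XVE>>AXR3-1 (556), although 92.7% and 90.6% of the latter's higher and lower genes had the same sign in HS::AXR3-1. The median SD of log2 CPM between the libraries of HS::AXR3-1 was 1.19 times that of XVE>>AXR3-1 (0.283 against 0.237), a ratio that did not decide. In the main fit all groups share 1 estimate of the spread per gene. A larger spread in HS::AXR3-1 thus enters both comparisons, and the ratio cannot show that it lowered the HS::AXR3-1 count alone. A lower level of AXR3 stays open, since the shift of these genes was 0.39 larger on the log2 scale in the HS::AXR3-1 library with the most AXR3 than in the one with the least, but that library had a smaller shift than XVE>>AXR3-1 replicate 1 (0.54 against 1.36) with more AXR3 (861 against 734 CPM). Within XVE>>AXR3-1 the shift was 1.36, 1.23 and 1.02 at 734, 939 and 1180 CPM. The changes of that line chose these genes, which tends to enlarge its shifts, so 0.54 against 1.36 does not decide. In HS::AXR3-1 the AXR3 level and the heat response had the same order over the 3 libraries, so the level of AXR3 and the strength of the heat treatment cannot be told apart.

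Splits of the libraries were counted for each comparison. With 6 libraries there are 10 splits, too few for a share under 0.05. As many genes as in the real split were found in 1 of 10 splits for IAA against mock (33 genes, highest other 0), PEO-IAA against mock (7, highest other 0), IAA against PEO-IAA (125, highest other 0), XVE>>AXR3-1 (556, highest other 0) and the heat check (306, highest other 0). In the paired experiments the 4 splits that part as many pairs gave at most 0 genes besides the real one, and the other splits keep some pairs together. For HS::AXR3-1 2 of 10 splits gave as many as the real 5 genes. The split of HS::AXR3-1 replicates 1 and 2 and Col-0 replicate 2 against the other ones gave 672, which points to a structure of the samples. The mean log2 CPM of the cell division list was 4.56, 4.68 and 4.65 in the first 3 libraries and 3.6, 4.19 and 4.05 in the others. Reads on organelle genes made up 0.0% of each of the first 3 libraries and 0.13%, 0.04% and 0.05% of the others in the same order. Both features were picked after the split was seen, and the cause was not tested.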
